A study of Mus musculus with 6 samples.

How the data were processed

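RNA was measured in colonic epithelial cells of C57BL/6J mice, enriched on a Percoll gradient, from 6 animals in 2 groups of 3. The knockout group carried the Nr3c1 knockout under the tamoxifen-inducible Vil-Cre/ERT2 transgene, whose villin promoter is active in intestinal epithelium. Per the labels' protocols, tamoxifen was injected on 5 consecutive days and cells were taken 7 days after the first injection, and non-stranded mRNA libraries were made with a TruSeq kit. The labels do not say which exon of Nr3c1 was deleted or whether the wild-type animals carried the transgene. FastQC, TopHat, DESeq2 and the mouse build mm10 are named in the submitters' processing notes without versions, and the read counter and the annotation are not given in the sources used here.

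The deposited table holds a normalized signal per gene and library: gene counts that the authors divided by 1 size factor per library, per the submitters' processing notes and the values themselves. In each column every value was a whole multiple of 1 step, and 100% of the values came out as whole reads within 0.001. The recovered reads number 10089313 to 12030844 per library. Rows are Entrez gene numbers, and 23666 of 23725 matched a gene symbol in the RefSeq table of GRCm38.p6, the assembly from which mm10 was made. Coordinates are those of GRCm38. Reads from overlapping or antisense genes cannot be told apart in non-stranded libraries, and reads of near-identical paralogs can have been shared or dropped by the counting.

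Differences were tested with limma 3.58.1 in R 4.3.3, using an intensity-dependent prior, on log2(value + 1) for the 12837 genes with a value of at least 10 in at least 3 of the 6 libraries. Benjamini-Hochberg adjustment was used with a threshold of 0.05. Every adjusted p of a gene is from this limma fit unless another tool is named, and a log2 change is on the log2(value + 1) scale, knockout minus wild type, which understates the change of low genes. Means and SDs are of the normalized values. A fold against a group with no read is a lower bound from a floor of 3 counts per library, and for genes with 1 to 3 reads in a group the ratio of summed reads is given with an exact 95% binomial interval, which covers counting error only. The single-gene test of Nr3c1 was a two-sided exact permutation test, whose smallest possible p with 3 against 3 libraries is 0.1.

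Of the gene lists, 31 were fixed before the data were examined. They cover glucocorticoid-induced genes, ion, bicarbonate and water transport, junctions and barrier, inflammatory mediators, antimicrobial defence, NF-kB, interferon-stimulated genes, MHC class II, cell cycle, stem cells, 4 epithelial cell types, 7 other cell sources, lipid oxidation, cholesterol and fatty acid synthesis, xenobiotic metabolism, steroid synthesis, the circadian clock, immediate early genes, stress responses, p53 targets, distal colon Hox genes and sex-linked transcripts. The 26 lists with at least 5 tested members were tested with camera at an inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over lists, and again with an estimated correlation and with fry. The genes named were set by a rule written at the same time: Nr3c1, Nr3c2 and Fkbp5, the 10 largest rises and the 10 largest falls past the threshold without overlap between the groups and with a mean of at least 50 in the higher group (predicted genes and pseudogenes passed over), and up to 3 members per list with the smallest adjusted p. Some genes that this rule names are not reported here. Other genes named are said to be chosen after their values were seen.

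The replicate numbers are names in accession order and pair nothing, and the labels give no batch. No replicate pair agreed within sampling noise, with a chi-square per degree of freedom of 14.7 to 56.9. Also tried, all chosen at the same time as the lists, were pseudocounts of 0.5 and 5, no filter and a filter at 50, TMM, upper-quartile and quantile scaling, robust empirical Bayes, library weights, a covariate of immune and stromal marker level, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, and leaving out each library. On data simulated from these 12837 genes and this comparison, with 200 changed genes, limma recovered 6% of genes changed 1.5-fold, 42% at 2-fold, 88% at 4-fold and 94% at 8-fold. Of the genes it called, 7.26% were unchanged ones, above the nominal 5%, against 8.73% for edgeR and 22.2% for DESeq2. These shares come from a single simulated data set and carry its counting error. In the real comparison 30.5% of the tested genes were called, so the simulated shares and recoveries need not carry over. Both changed lists and 0 of 20 unchanged lists were called by camera in the simulation. The changed lists held only changed genes and all genes were drawn independently, so this does not test camera on correlated genes.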

Results

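Gene expression was compared between colonic epithelial cells of 3 wild-type mice and 3 mice with an inducible, intestinal epithelium-specific knockout of Nr3c1, the gene of the glucocorticoid receptor. The comparison asks which genes differ between these cells with and without the receptor. The labels do not say whether the wild-type animals carried the Cre transgene, so its effect with tamoxifen is not separated from that of receptor loss. Each group had n = 3 libraries, and values are normalized reads, given as mean ± SD. Recovered reads per library ranged from 10089313 to 12030844. Libraries of one group correlated across genes, which are not independent replicates, at 0.96 to 0.982 and those of different groups at 0.848 to 0.941. The first principal component held 77% of the variance and separated the groups.

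Nr3c1 itself (Entrez 14815, GRCm38 chromosome 18, 39410545 to 39519421) was low in every library labelled knockout, with 144.7, 123.1 and 174.7 normalized reads. It was 1120 and 967.1 in the libraries labelled wild type replicates 1 and 2, but 196.7 in the library labelled wild type replicate 3. That library therefore goes against its label at the targeted gene, and every direction below includes it among the libraries labelled wild type. Across the groups Nr3c1 fell from 761 ± 495 to 147.5 ± 25.9 (log2 change -2.03, SE 0.60, limma adjusted p = 0.0372), and the exact permutation p was 0.1, the smallest possible. Without the library labelled wild type replicate 3 the change was -2.83 (limma adjusted p = 0.000731). Leaving out wild type replicate 1, wild type replicate 2, knockout replicate 1, knockout replicate 2 or knockout replicate 3 ended the call (limma adjusted p = 0.121, 0.125, 0.0631, 0.0816 and 0.0733), as did a covariate of immune and stromal marker level (log2 change -0.73, adjusted p = 0.863). The counts are per gene and can include reads from exons that stay after the deletion.

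**Figure D1:**
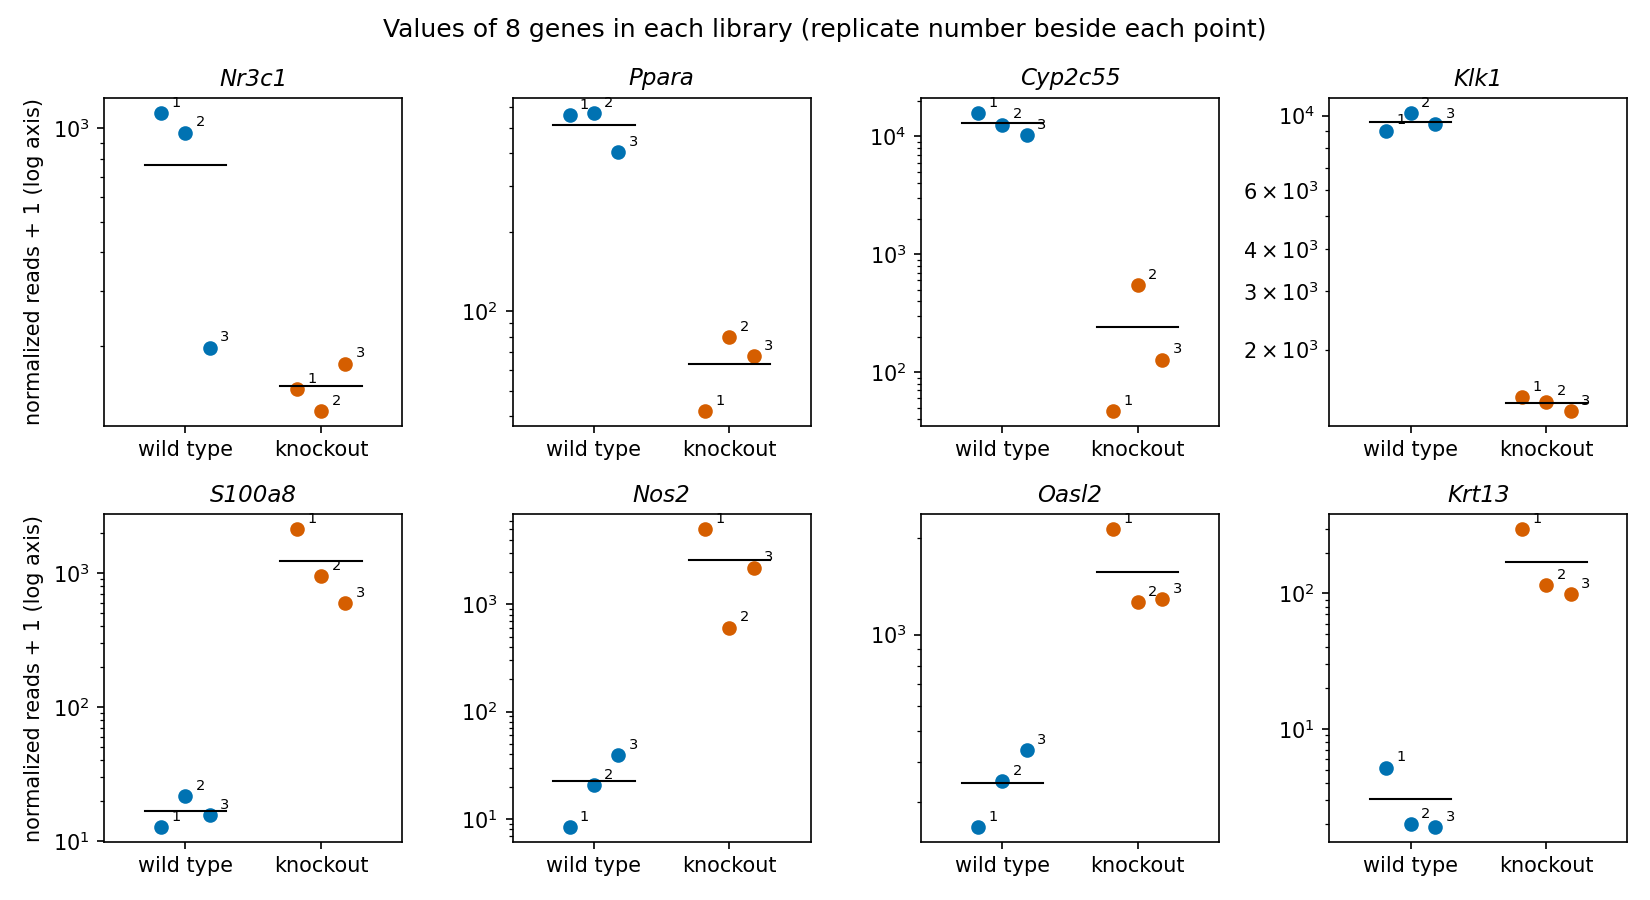
Normalized reads plus 1 on a log axis for 8 genes in each of the 6 libraries. Points are libraries with their replicate number, and lines are group means. The library labelled wild type replicate 3 lies at 196.7 for Nr3c1, near the knockout libraries. For the other 7 genes it lies on the side of the other wild-type libraries. These 7 genes were named by rules that counted it as wild type and favoured separated groups, so their side says nothing about its label.

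Of 12837 genes tested, 3910 changed, 1931 upward and 1979 downward in the knockout libraries. At least a 2-fold change was seen for 878 raised and 986 lowered genes. Among the largest rises were Nos2, the inducible nitric oxide synthase, from 21.8 ± 15.5 to 2603 ± 2232, Lrg1, a secreted glycoprotein of acute inflammation, from 17.9 ± 11.7 to 1820 ± 925, and S100a8, a subunit of the neutrophil protein calprotectin, from 15.6 ± 4.52 to 1227 ± 801. Ly6d rose from 9.32 ± 4.89 to 1406 ± 1455, the protease gene Prss22 from 1.97 ± 0.15 to 436 ± 270, and Krt13, a keratin of stratified epithelium, from 2.05 ± 1.91 to 169 ± 111. Gml had no read in the 3 wild-type libraries and 107.5 ± 30.4 in the knockout, at least 33.8-fold higher. Gml2, Acsbg1 and the collagenase gene Mmp8 had 1 read each in the wild-type libraries together, and their ratios of reads were 276 (interval 49 to 10900), 275 (48.8 to 10900) and 244 (43.3 to 9660). The adjusted p of these 10 genes ranged from 0.000107 to 0.00199.

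Several enzyme genes were among the largest falls. Cyp2c55, a cytochrome P450, fell from 12890 ± 2802 to 241 ± 270. The glucuronosyltransferase genes Ugt2b5 and Ugt2b38 fell from 620 ± 163 to 7.60 ± 4.64 and from 221 ± 61 to 2.32 ± 1.41, and Ugt2b37, with 2 reads left in the knockout libraries, had a wild-type to knockout ratio of 163 (interval 44.7 to 1350). These are close paralogs whose reads may be shared. Arhgap20 (426 ± 115 to 6.99 ± 3.39), the transporter gene Slc16a9 (210 ± 113 to 4.35 ± 4.16), Fndc5 (112 ± 44.3 to 1.69 ± 1.58), the carboxylesterase gene Ces1d (667 ± 304 to 18.7 ± 19.9) and Nacad (100.3 ± 23.8 to 1.68 ± 0.55) also fell, and the adjusted p of the lowered genes named here ranged from 0.000225 to 0.00387. Without wild type replicate 1 the count of changed genes was 1923, and without wild type replicate 2 it was 1960. Without the library labelled wild type replicate 3 it was 3228, of which 3003 were among the 3910. With the level of immune and stromal markers as a covariate 90 genes changed, and 61 of the 3910 turned direction. That level correlated with genotype at 0.843 over the 6 libraries, so this fit cannot well separate marker level from genotype.

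**Figure D2:**
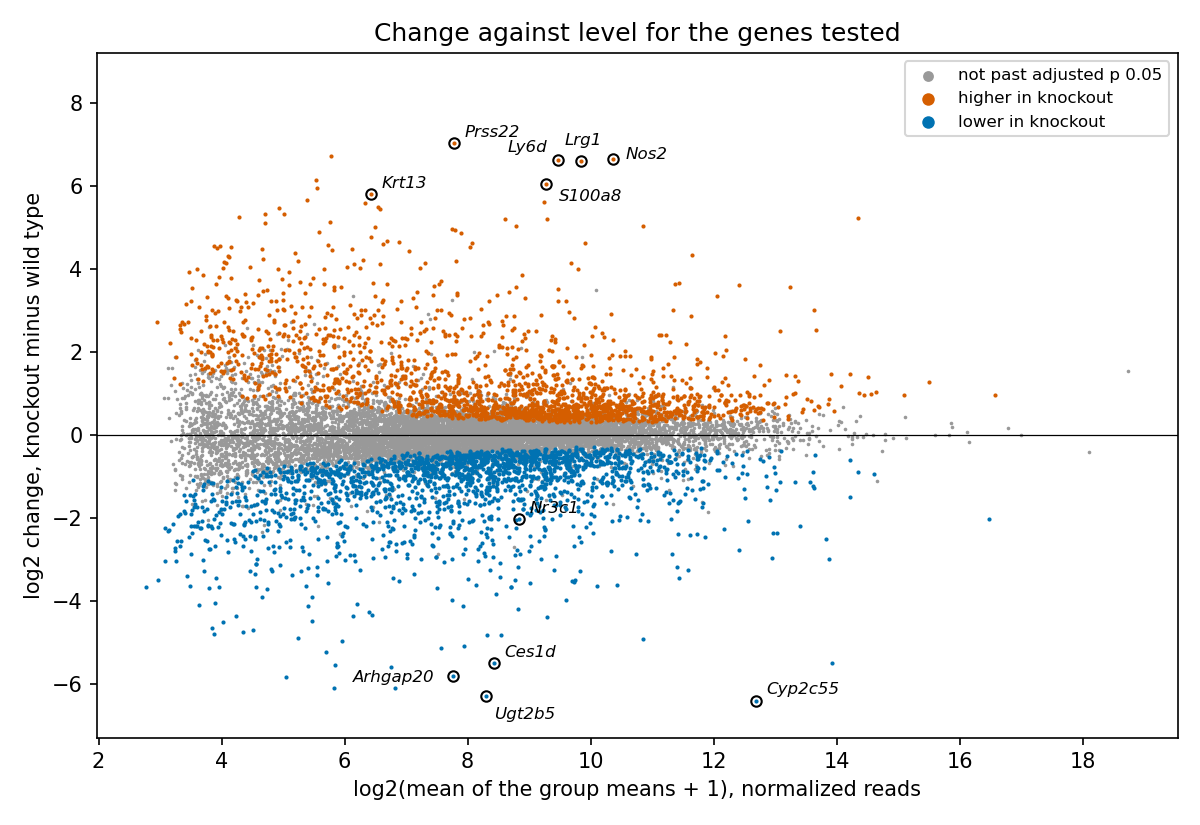
Log2 change, knockout minus wild type, against the level of each gene, for the 12837 genes tested. Points are genes, coloured where the adjusted p is under 0.05 (1931 raised and 1979 lowered), and circles mark named genes.

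Most of the inflammatory genes tested rose. Of 31 tested inflammatory mediators 22 rose and 2 fell, and adjusted over the list alone 23 rose and 2 fell. S100a9, the partner of S100a8, rose from 17.7 ± 1.14 to 1189 ± 1017 and the chemokine gene Ccl20 from 8.17 ± 0.33 to 77.4 ± 9.27 (limma adjusted p = 0.000919 and 0.000445). Of 21 genes of antimicrobial and mucosal defence 12 rose and 2 fell (adjusted over the list alone 13 and 3), among them the protease inhibitor gene Slpi (76 ± 36.5 to 1852 ± 869), the secreted phospholipase gene Pla2g2a (23.2 ± 7.81 to 263 ± 90.5) and the oxidase gene Nox1 (142 ± 8.37 to 432 ± 91.5). Of 35 interferon-stimulated genes 18 rose and 0 fell (adjusted over the list alone 21 and 1), with Oasl2 going from 344 ± 92.5 to 1563 ± 496, Ifit1 from 231 ± 25.2 to 924 ± 384 and Oasl1 from 408 ± 60.5 to 1170 ± 306. Of them 13 rose without wild type replicate 1 or wild type replicate 2, and 22 without the library labelled wild type replicate 3. Without knockout replicates 1, 2 and 3 the numbers were 16, 28 and 15. The inflammatory mediators raised numbered 15 to 22 with 1 library left out, lowest without wild type replicate 2 (15) and wild type replicate 1 (16). Of the antimicrobial genes 0 fell without wild type replicate 1, knockout replicate 2 or knockout replicate 3, and 1 without wild type replicate 2 or the library labelled wild type replicate 3. The mean log2 level of 37 immune and stromal markers moved with these groups, being 4.45, 4.86 and 5.5 in the wild-type libraries and 7.15, 5.8 and 6.5 in the knockout libraries. With this level, which includes S100a8, S100a9 and Ccl5 of the inflammatory list, as a covariate 5 inflammatory, 3 antimicrobial and 0 interferon-stimulated genes rose. The median log2 change of the interferon list went from 1.32 to -0.116 and that of the inflammatory list from 2.11 to 0.72. The median of the antimicrobial list stayed at 1.14.

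In the NF-kB list, 7 of 25 members rose and 2 fell (adjusted over the list alone 8 and 3). Tlr4, a receptor for bacterial lipopolysaccharide, rose from 199 ± 72 to 466 ± 79.3, while the flagellin receptor gene Tlr5 fell from 75.4 ± 24.7 to 7.61 ± 4.29 and Traf1 from 205 ± 9.17 to 43.7 ± 3.91. The number raised was 1 without wild type replicate 1, 1 without wild type replicate 2, 3 without knockout replicate 1 and 3 without knockout replicate 3. No MHC class II gene of 9 passed the threshold, while 3 rose without the library labelled wild type replicate 3 and 1 without knockout replicate 2. H2-Eb1 was 68.8 ± 48.8 and 174 ± 96.1 (limma adjusted p = 0.101).

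Many genes of lipid and foreign-compound metabolism fell. Of 26 genes of lipid oxidation and PPAR targets 17 fell and 4 rose (adjusted over the list alone 17 and 5), including the nuclear receptor gene Ppara (510 ± 92.9 to 62.1 ± 19.3) and the fatty acid-binding protein gene Fabp2 (5657 ± 560 to 1106 ± 332). Of 24 xenobiotic metabolism genes 11 fell and 2 rose (adjusted over the list alone 14 and 4), with Cyp2c65 going from 4881 ± 956 to 546 ± 201 and Aldh1a1 from 4551 ± 190 to 1839 ± 312. Of the xenobiotic genes 7 fell without wild type replicate 1 or without wild type replicate 2, and 1 rose without wild type replicate 2 or with quantile normalization. In the list of steroid synthesis and nuclear receptors 7 of 12 fell and 0 rose (adjusted over the list alone 9 and 0). The members that fell most clearly were the steroid dehydrogenase genes Hsd3b2 (1541 ± 169 to 146 ± 81.1) and Hsd3b3 (5031 ± 588 to 519 ± 302), which are paralogs, and Nr5a2 (738 ± 183 to 230 ± 59.5), a nuclear receptor that drives intestinal glucocorticoid synthesis. The steroid synthesis genes Cyp11a1, Cyp11b1 and Star of this list were too low in both groups to be tested. Without wild type replicate 1, 3 of the 12 fell. With the immune and stromal marker covariate 2 lipid oxidation, 2 xenobiotic and 0 steroid genes fell. The median log2 changes of these lists went from -0.855 to -0.387, from -0.667 to -0.0326 and from -0.588 to -0.344. Of 24 genes of cholesterol and fatty acid synthesis 4 rose and 1 fell (adjusted over the list alone 2 and 0), with Fdps at 2299 ± 357 and 3600 ± 561 and Idi1 at 2205 ± 382 and 3150 ± 210. The number raised was 1 without wild type replicate 1, 1 without wild type replicate 2, 1 without knockout replicate 3 and 2 with quantile normalization. The number lowered was 3 without knockout replicate 3 and 0 without any 1 of the wild-type libraries.

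Known glucocorticoid-induced genes moved in both directions. Of 28 tested 8 fell and 4 rose, also when adjusted over the list alone. The sulfotransferase gene Sult1a1 fell from 3542 ± 864 to 145 ± 105 and the pyruvate dehydrogenase kinase gene Pdk4 from 614 ± 319 to 20.9 ± 11.6, while the mTOR inhibitor gene Ddit4 rose from 647 ± 170 to 2372 ± 56.7. Fkbp5, a widely used glucocorticoid target, did not pass the threshold at 3530 ± 302 and 2518 ± 1222 (log2 change -0.62, SE 0.35, limma adjusted p = 0.205), with knockout values of 1237, 3670.1 and 2648.3. Nr3c2, the gene of the mineralocorticoid receptor, fell from 975 ± 126 to 640 ± 56.7 (limma adjusted p = 0.013). Without wild type replicate 1, 2 rose and 5 fell, without wild type replicate 2, 5 fell, and without knockout replicate 1, 7 rose. With library weights 8 rose and 8 fell. The camera test of the list gave an adjusted p of 0.358.

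Of 33 genes of ion, bicarbonate and water transport 11 fell and 2 rose (adjusted over the list alone 12 and 2). The bicarbonate cotransporter gene Slc4a4 fell from 973 ± 144 to 167 ± 41, the monocarboxylate transporter gene Slc5a8 from 4242 ± 356 to 1394 ± 133 and the potassium channel gene Kcnq1 from 1094 ± 156 to 356 ± 76. Without knockout replicate 1, 4 rose. Junction and barrier genes were mixed, with 6 of 29 raised and 6 lowered, also when adjusted over the list alone. Cldn23 fell from 3861 ± 367 to 1308 ± 193 and Cldn15 from 1485 ± 487 to 484 ± 133, whereas the desmosomal gene Pkp3 rose from 1468 ± 228 to 2543 ± 265. The raised junction genes numbered 1 without wild type replicate 1, 2 without wild type replicate 2 and 3 without knockout replicate 3, and the lowered ones 3 without wild type replicate 1.

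Among epithelial cell types, 6 of 19 goblet cell markers fell, 1 rose and 12 did not pass the threshold, with the same counts raised and lowered when adjusted over the list alone. Of these, 3 were lowered without wild type replicate 1 or without wild type replicate 2, and 2 raised without wild type replicate 2, without knockout replicate 1, with library weights or with DESeq2. The mucin gene Muc2 fell from 28350 ± 8880 to 9662 ± 1363 and Klk1 from 9552 ± 592 to 1383 ± 64.2, while Sytl2 rose from 466 ± 16 to 726 ± 30.1. Klk1 had the smallest unadjusted p of any gene tested (limma adjusted p = 4.26e-05) and its log2 change was -2.79. Colonocyte markers went both ways, 6 of 23 up and 6 down, also when adjusted over the list alone, with falls of Guca2a (24370 ± 6282 to 4521 ± 2456) and Phgr1 (8627 ± 1706 to 3004 ± 565). Of 10 enteroendocrine markers 3 rose and 1 fell, also when adjusted over the list alone, the rises being the peptide hormone genes Pyy (39.3 ± 5.64 to 203 ± 48.9) and Insl5 (33 ± 8.18 to 128 ± 51.7) and the prohormone-processing gene Cpe (35.6 ± 18.9 to 155 ± 10.6). Without the library labelled wild type replicate 3, 3 of them fell, but 0 without wild type replicate 1, wild type replicate 2, knockout replicate 2 or knockout replicate 3. Of 7 tuft cell markers 3 rose and 1 fell (adjusted over the list alone 3 and 2), with Avil (17.5 ± 4.12 to 99.2 ± 50.4) and Alox5ap (17.4 ± 10.1 to 89.4 ± 28.4) among those raised. No tuft cell marker fell without wild type replicate 1, wild type replicate 2 or knockout replicate 3.

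Of 28 cell cycle genes 9 rose, 0 fell and 19 did not pass the threshold, and 13 rose when adjusted over the list alone. Rrm2, a subunit of ribonucleotide reductase, rose from 235 ± 99.5 to 754 ± 409, Ccna2 from 610 ± 210 to 1194 ± 246 and Birc5 from 239 ± 94.5 to 526 ± 145. This count depended on single libraries and was 0 without wild type replicate 1, 0 without wild type replicate 2, 2 without knockout replicate 1 and 4 without knockout replicate 2, and 15 with DESeq2. With the immune and stromal marker covariate 0 cell cycle genes rose, and the list median of the log2 change was 0.315 against 0.909. Of 17 stem cell genes and Wnt targets 0 rose and 4 fell, also when adjusted over the list alone, among them Sox9 (664 ± 89.2 to 261 ± 58.1), Znrf3 (103 ± 7.79 to 46.8 ± 3.44) and Axin2 (214 ± 28.4 to 124 ± 31.6). Without wild type replicate 1 or wild type replicate 2, 2 fell.

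Of 20 immediate early genes, which also respond to tissue dissociation, 10 fell and 3 rose (adjusted over the list alone 10 and 4). Fosb fell from 17800 ± 3447 to 3827 ± 560 and Jun from 18010 ± 3354 to 7314 ± 1110, and Ier3 rose from 322 ± 44.6 to 1037 ± 326. Without wild type replicate 1, 1 rose. In the unfolded protein and integrated stress response 10 of 20 rose and 2 fell (adjusted over the list alone 12 and 3), led by the serine synthesis genes Phgdh (142 ± 40.6 to 614 ± 168) and Psat1 (97.8 ± 40.5 to 494 ± 146) and the asparagine synthetase gene Asns (333 ± 32.8 to 785 ± 177). The number raised was 6 without wild type replicate 1 and 4 without wild type replicate 2. Of 20 p53 targets and apoptosis genes 7 rose and 1 fell (adjusted over the list alone 7 and 2), with Phlda3 at 14.2 ± 5.16 and 164 ± 93.4, Eda2r at 7.88 ± 3.52 and 55 ± 24.1 and Bcl2l1 at 507 ± 22.8 and 915 ± 169. Of the p53 targets 4 rose and 0 fell without wild type replicate 1 or without wild type replicate 2. Of 16 circadian clock genes 4 fell and 1 rose, also when adjusted over the list alone, with Nfil3 (828 ± 243 to 288 ± 40.5), Arntl (686 ± 61.9 to 347 ± 78.5) and Nr1d1 (1816 ± 626 to 830 ± 168) among the lowered. Of the clock genes 2 fell without wild type replicate 1 or wild type replicate 2, while 2 rose without knockout replicate 1 and 0 without wild type replicate 1, wild type replicate 2, knockout replicate 2 or knockout replicate 3.

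Several markers of other cell types rose. Of 16 myeloid markers 11 rose and 0 fell (adjusted over the list alone 12 and 0), including S100a8, S100a9 and the Fc receptor gene Fcgr3 (8.04 ± 2.44 to 104 ± 49.3), of which S100a8 and S100a9 are also in the inflammatory list. The raised myeloid markers numbered 8 without wild type replicate 1, wild type replicate 2, knockout replicate 1 or knockout replicate 3. They numbered 12 without the library labelled wild type replicate 3 and 15 without knockout replicate 2. Of 9 T cell and intraepithelial lymphocyte markers 2 rose, also when adjusted over the list alone, namely Cd52 (10.3 ± 4.59 to 55.5 ± 11.9) and Ptprc (42.3 ± 8.49 to 157 ± 82.4). Without knockout replicate 2, 4 rose. The T cell list has 20 members, and Cd3e, Cd3d, Cd3g, Cd8a and Cd4 were among those too low to be tested. The rises of Cd52 and Ptprc alone therefore do not show more T cells. Of 11 stromal, muscle and endothelial markers 2 rose (adjusted over the list alone 1), namely Vim (77.9 ± 29.9 to 236 ± 69) and Dcn (37.5 ± 26.7 to 187 ± 146). Of the stromal markers 5 rose without knockout replicate 2, and 1 without any of the other knockout libraries, wild type replicate 1 or wild type replicate 2. Together these markers held 0.0156%, 0.0209% and 0.0291% of the reads in the wild-type libraries and 0.105%, 0.0438% and 0.052% in the knockout libraries. The single tested B and plasma cell gene, Jchain, was 39 ± 31.6 and 110 ± 64.3 (limma adjusted p = 0.132). Ret, the single tested gene of the enteric neuron and glia list, rose from 15.6 ± 7.15 to 455 ± 51.4. Of 4 blood cell genes the platelet gene Pf4 rose (4.77 ± 2.58 to 34.1 ± 3.9), and of 2 pancreas genes Cela1 fell (1385 ± 332 to 386 ± 88.7). Of the pancreas genes too low to be tested, Amy2a5 was 68.1 and 15.5 in knockout replicates 1 and 2 and 0 in the other libraries, and without the filter the list median was 1.08 against -0.872. Of 6 distal colon Hox-list genes Hoxd13 (72.5 ± 28 to 219 ± 55.4) and Hoxa13 (87.4 ± 19.6 to 188 ± 80.9) rose and 1 gene fell, and adjusted over the list alone 3 rose and 1 fell. Of these 1 rose without wild type replicate 1, wild type replicate 2, knockout replicate 2 or knockout replicate 3, and 4 with library weights. No sex-linked transcript of 4 passed the threshold, although 1 fell without knockout replicate 3, and Xist was 2495 ± 448 and 1583 ± 643 (limma adjusted p = 0.0778).

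**Figure D3:**
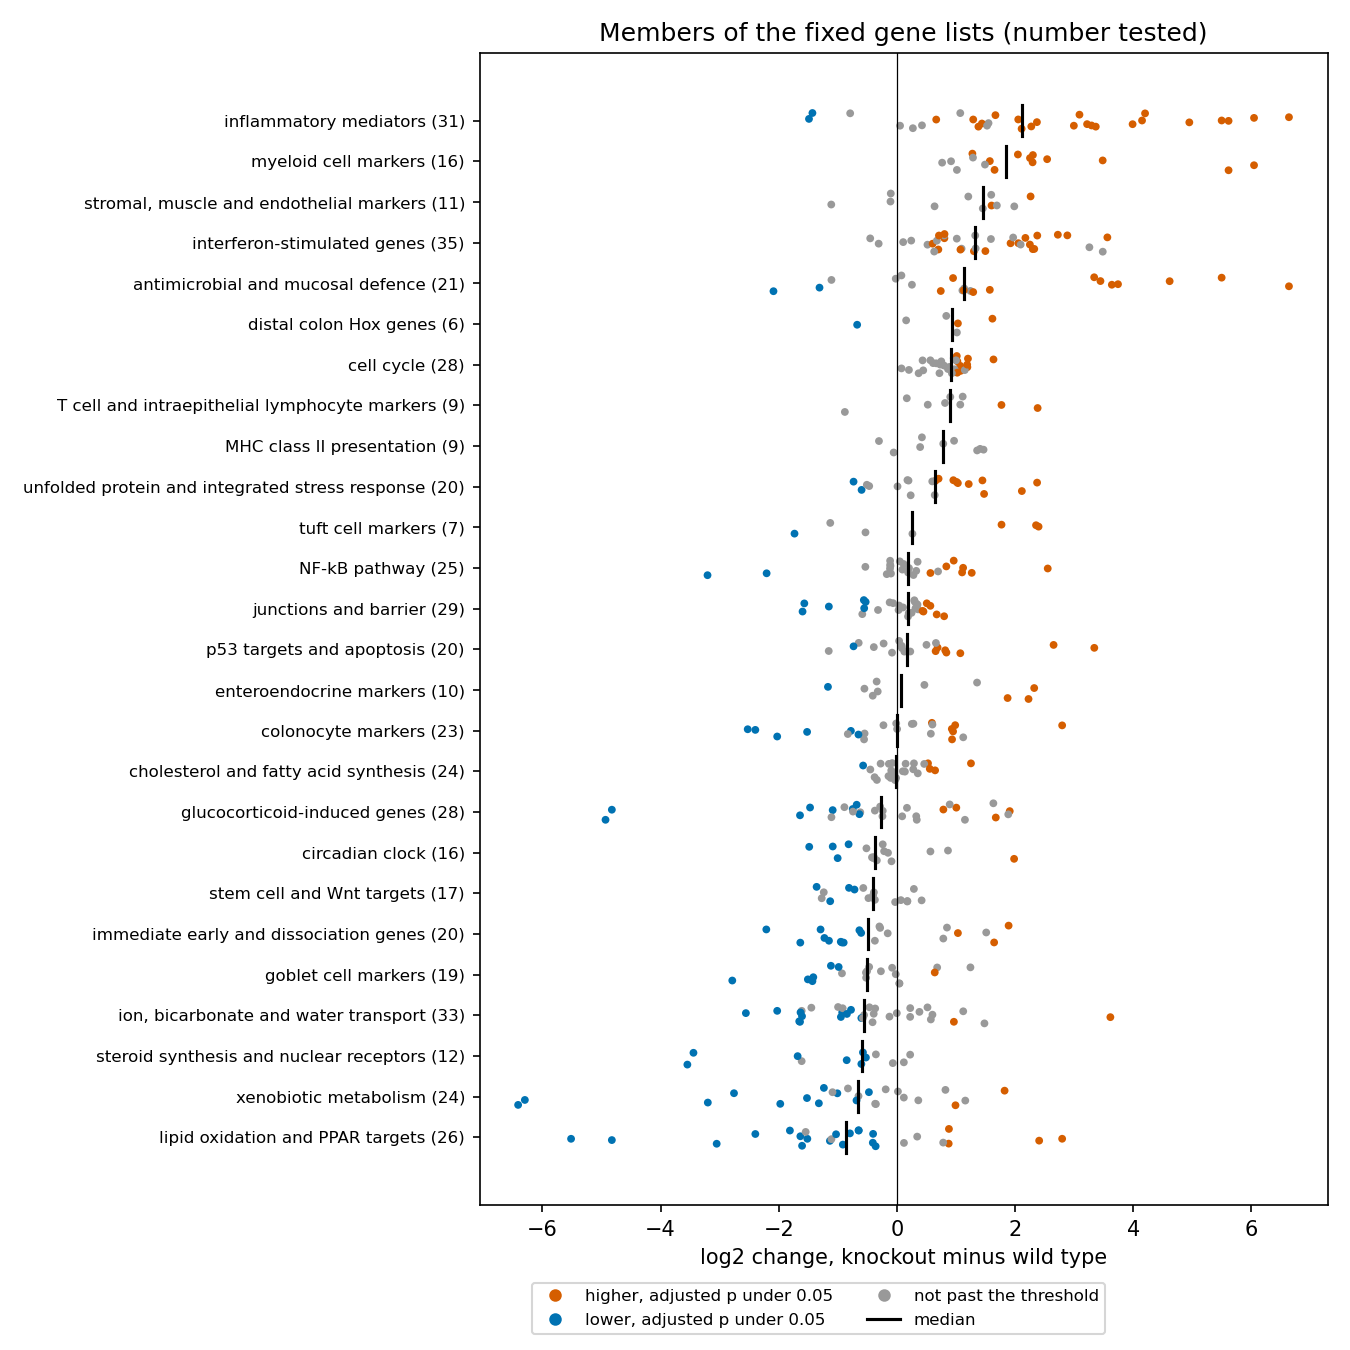
Log2 change, knockout minus wild type, of each tested member of the 26 lists tested with camera. Points are genes, coloured where the adjusted p is under 0.05, bars are list medians, the number tested is in parentheses, and inflammatory mediators have a median of 2.11 and genes of lipid oxidation and PPAR targets one of -0.855.

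Tested as sets, 6 lists were higher and 6 lower by camera. The higher lists were inflammatory mediators (adjusted p = 2.09e-07), interferon-stimulated genes (2.49e-07), myeloid markers (2.02e-06), cell cycle (3.47e-05), antimicrobial defence (0.000294) and the unfolded protein and integrated stress response (0.0125). The lower lists were lipid oxidation (adjusted p = 0.000724), steroid synthesis and nuclear receptors (0.0011), xenobiotic metabolism (0.0053), ion transport (0.0146), immediate early genes (0.026) and goblet cell markers (0.0482). All 12 calls were lost with an estimated correlation, where each of these lists had an adjusted p = 0.705, and 6 of the 12 passed with fry, namely inflammatory mediators, antimicrobial defence, myeloid markers, lipid oxidation, steroid synthesis and immediate early genes. Stem cell genes and Wnt targets (adjusted p = 0.0349) and p53 targets (0.0165) passed with fry alone. For junctions and barrier the median (0.188) and the camera direction were upward and the mean (-0.0283) downward, for colonocyte markers the same held with a median of 0.00294 and a mean of -0.0894, and for cholesterol synthesis the median was -0.0229 and the mean 0.0849 with camera upward.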

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

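All alternatives given here were planned before the data were examined. The counts of 3910 changed, 1931 raised and 1979 lowered genes stayed within 1.5 times under every scaling, pseudocount, filter and tool tried (3328 to 4164 changed, with 3893 by edgeR and 4164 by DESeq2), and no main call turned its direction in these settings. A required change of 2-fold left 1864, 878 and 986 by its construction. Leaving out 1 library gave 1923 to 3607 changed, 970 to 1782 raised and 953 to 1825 lowered genes, lowest without wild type replicate 1 (1923) and wild type replicate 2 (1960), for which the cause was not tested. The Nr3c1 change ranged from -2.83 to -1.57 (limma adjusted p 0.000731 to 0.125). The immune and stromal marker covariate, correlated with genotype at 0.843, left 90 changed, 41 raised and 49 lowered genes, reversed 61 of the 3910, moved Nr3c1 to -0.73, left 7 lists past the threshold against 12 without it, and turned the changes of H2-Eb1 (-0.58), Dcn (-0.47) and Fkbp5 (0.35). With it the camera direction turned for the lists of glucocorticoid-induced genes (adjusted p 0.789), junctions (0.203), NF-kB (0.388), MHC class II (0.0678), goblet cells (0.78), T cells (0.486), stromal cells (0.000926) and the circadian clock (0.643). The colonocyte list turned with no filter (0.907), quantile normalization (0.834), edgeR (0.845), DESeq2 (0.836) and fry (0.997), and leaving out libraries gave 0.394 to 0.937, turned without wild type replicate 1 and knockout replicate 2. Quantile normalization turned the junction list (0.906) and no filter the tuft cell list (0.882). Leaving out libraries gave 0.0354 to 0.948 for MHC class II and 0.166 to 0.829 for cholesterol synthesis, turning the first without wild type replicate 2 and the second without knockout replicate 3. With an estimated correlation 0 lists passed, and the cause of the other turns was not tested. Of 1608 values of 95 named genes outside the covariate 1571 kept direction and side of the threshold, 33 lost it, 4 gained it and 0 turned. Most of the named genes were picked for large or clear changes in the main fit, which favours their keeping a call. Of all 3910 calls, 1916 stayed without wild type replicate 1 and 1949 without wild type replicate 2. Of 492 values of 26 lists outside the covariate 444 kept direction and side of the threshold, 26 lost the threshold, 11 gained it and 11 turned. The lists were not picked by their result, so the shares of genes and lists are not comparable. Depth limits genes with few reads, whose ratios carry wide intervals.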

Other observations

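Chosen after the result was seen were the tests on the splits of the samples, on the library labelled wild type replicate 3, on the shares of cell types and on Hox genes. The tests on squamous keratins, on hypoxia and glycolysis genes and on oxidative phosphorylation were written before their values were looked at, although single genes had prompted them. The genes named here were chosen after their values were seen.

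Many genes of glycolysis and of the response to low oxygen rose, in the same libraries in which the mean log2 level of immune and stromal markers was higher (4.45 to 5.5 in wild type, 5.8 to 7.15 in the knockout). Egln3 (298 ± 21.5 to 2264 ± 359), Ak4 (217 ± 81.9 to 1485 ± 193) and Mif (452 ± 25.4 to 1386 ± 89.3, n = 3 per group) rose and, with Ddit4, prompted a list of 30 other tested genes. Of these 19 rose and 2 fell, against 15% of all tested genes raised, among them Bnip3 (121 ± 22.5 to 743 ± 209), Pfkfb3 (19.5 ± 8.81 to 506 ± 278), Slc16a3 (97.7 ± 47.4 to 882 ± 46.2) and Pkm (12890 ± 1348 to 33770 ± 2089). Camera gave p = 5.88e-08, and p = 0.0641 with an estimated correlation. In fits added after the data were seen, 16 to 21 of the 30 rose with 1 library left out, and 2 rose with the marker covariate, where the median log2 change was 0.762 against 0.76. A hypothesis is that these genes rose as a group, which the 19 members are in line with. Nuclear genes of oxidative phosphorylation, tested as a counterpart, gave no answer: 12 of 78 fell and 0 rose, against 15.4% of all genes lowered, so that the written bound for a negative outcome was met by less than the spread of the share, while camera gave p = 1.2e-05 downward and p = 0.48 with an estimated correlation.

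The kallikrein genes of the Klk1 cluster (GRCm38 chromosome 7, 43950666 to 44229622) all fell, 13 of 13 tested, by log2 changes of -3.41 to -2.79. Reads of these paralogs can have been shared, and Klk1b1 and Klk1b16 had nearly the same reads in every library (293 and 293 in wild type replicate 1), so the values of the separate genes are uncertain. Among 241 symbol stems with at least 8 tested genes, all of which were scanned, the Ugt stem had 11 of 12 genes lowered, Hoxb 7 of 8, Stard 6 of 8 and Hsd 11 of 16, and Cxcl had 7 of 8 raised, Mmp 7 of 10 and the proteasome stem Psmd 10 of 14. These stems were picked from the scan for their large shares.

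The number of changed genes cannot be set against chance by splits of the samples, since the 6 libraries allow only 10 and the share cannot fall under 0.05. The real split gave 3910 changed, 1931 raised and 1979 lowered genes, was the only 1 of the 10 to reach each of these counts, and the highest of the other splits was 0 in each case. For lists past the camera threshold 4 of the 10 splits gave at least the 12 of the real one, and the highest gave 19. Every other split put libraries of both genotypes on each side. Part of the genotype difference thus stayed between the sides, and part added to the spread within them. Neither the gene counts nor the list counts of those splits therefore show what chance gives.

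The low Nr3c1 of the library labelled wild type replicate 3 was weighed against 3 explanations. A swap of 2 libraries needs a library labelled knockout with Nr3c1 at the level of wild type replicates 1 and 2 (1120 and 967.1), and the highest was 174.7. A knockout animal in the knockout expression state is argued against by the other genes: over the 3228 genes changed without this library its median position was 0.254 on a scale from the other wild-type libraries (0) to the knockout libraries (1), where at least 0.75 was required, and 3.31% of the genes reached 0.75. The median missed the written bound for exclusion, 0.25, and the exclusion rests on the upper quartile of 0.409, a criterion chosen after the result. Measured alike from its own group (0) to the other group (1), knockout replicate 2 lay at 0.266 and knockout replicate 3 at 0.187. Knockout replicate 1 and wild type replicates 1 and 2 lay at -0.274, -0.0851 and -0.0528. A median of about this size was therefore also seen in a knockout library, but among the wild-type libraries only the one labelled replicate 3 lay toward the other group. Each position rests on its own set of changed genes (1923 to 3607) and its own reference libraries, so the positions are only roughly comparable. It may be that Nr3c1 was deleted here while other expression had not followed, since Nr3c1 itself lay at 0.849, but reads over the deleted exon were not analysed here and a partly affected animal stays open, as does a biological difference between the animals.

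The rise of inflammatory and myeloid genes was weighed against cell makeup, which the tests leave open. A lower share of epithelial cells raises the markers of all other types alike, and the median log2 change was 1.85 for 16 myeloid markers and 1.11 for 21 T cell, B cell and stromal markers, a difference of 0.736 (permutation p over genes, which are not independent = 0.012). This difference does not exclude it: the permutation p was 0.14 without S100a8 and S100a9, which belong to the pattern itself, 0.2 against stromal markers alone, 0.11 without the library labelled wild type replicate 3 and 0.16 without knockout replicate 2. More myeloid cells in the knockout preparations stay a candidate source of the inflammatory list. With the marker covariate 5 of the 22 raised members of that list stayed past the threshold and 21 stayed higher in the knockout. These counts decide nothing, since the covariate includes S100a8, S100a9 and Ccl5 of that list and correlates with genotype at 0.843. An effect of the genotype on the epithelial cells themselves remains open beside both.

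Genes of stratified epithelium and of position along the gut may reflect which stretch of tissue was taken, and the tests leave this open beside the genotype as a biological cause. Anorectal squamous epithelium brings Krt5 and Krt14, whose summed rise was 0.509 of that of Krt13, between the bounds set for the ratio. The written outcome in favour also required both keratins to pass the threshold. It could not be reached, since Krt5 (means 1.56 and 18.6) was too low to be tested, and Krt14 had a limma adjusted p of 0.0749. The ratio of 0.509 rests on knockout replicate 1: it was 0.222 without that library, under the bound of 0.25 for exclusion. For the knockout libraries taken singly it was 0.71, 0.123 and 0.338, a spread on both sides of the bound. These leave-out and single-library values were chosen after the result was seen. Other squamous markers, among them Krt4, Trp63 and Krtdap, were too low to be tested. Of 9 squamous keratinocyte markers tested 1 rose (Krt6a, 12.3 ± 8.33 to 140.5 ± 153, with knockout values of 316.6, 37.2 and 67.8), and of the distal Hox list, which a more distal stretch of colon needs to rise together, 2 members rose and 1 fell.

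Over all 18 Hox genes the median log2 change of paralog groups 10 to 13 exceeded that of groups 1 to 9 by 2.12 (permutation p over genes = 0.014), and outside the Hoxb cluster by 0.871 (exact permutation p = 0.048), but the fall of Hoxb genes and the rise of Hoxd13, Hoxa10 and Hoxa13 had prompted both comparisons and the division into groups, so they do not bear out the hypothesis of a shift by paralog group.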
